A study of Zea mays with 6 samples.

How the data were processed

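RNA from developing maize endosperm at 20 days after pollination was sequenced for wild type (inbred B73) and for the nacRNAi line, with 3 libraries per line. Total RNA was extracted with TRIzol and purified with an RNeasy kit and DNase, and libraries were made with a Truseq mRNA kit, per the labels' protocols, which do not say whether strand was kept. Lines and replicate numbers were taken from the sample titles. The series holds a single contrast, nacRNAi against wild type.

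The authors deposited a table of raw read counts per gene and a table of FPKM values per gene, each with 6 library columns beside gene positions, descriptions, GO terms and pathways, per the file headers. The count values are whole numbers with no normalization. The FPKM values, which the authors scaled by gene length and library size, were estimated separately from the counts, since in each library between 253 and 280 genes had an FPKM above 0 at a count of 0. The aligner, the counter, the genome build and the annotation release are not given in the sources used here, so coordinates are printed as the files give them with the build unnamed. The table lists 39179 protein-coding genes, 39005 with Zm00001d identifiers and 174 with GRMZM identifiers. Names and descriptions came from the files. A reference table of the assembly Zm-B73-REFERENCE-NAM-5.0 matched 0 of the identifiers directly.

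Counts were the main measurement. Totals per library ran from 55812999 to 69670876. A count of 0 allows up to 3 counts, which is 0.0362 to 0.0625 TMM-scaled CPM per library, and such floors and the binomial intervals (Wilson, 95%) cover counting error only, since PCR duplicates are not independent molecules. No libraries of a line agreed within sampling noise. The chi-square per degree of freedom between replicates was 25.8 to 49.9, so each library counted as 1 sample.

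Genes were filtered with filterByExpr and scaled by TMM (factors 0.831, 0.806 and 0.872 in wild type and 1.191, 1.183 and 1.214 in nacRNAi). They were tested with the quasi-likelihood test of edgeR 4.0.16 (robust, line as the only term, all 6 libraries) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg, with 0.05 as the threshold. CPM values in the text are TMM-scaled. An SE is approximate: it is the absolute log2 fold change divided by the square root of edgeR's F statistic. Exact permutation tests are two-sided and cannot go below 0.1 with 3 against 3 libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.

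Before the data were examined, 25 gene lists were fixed by identifier, symbol or description pattern, covering the targets, storage products, pathways and markers of other kernel parts. After the files were read, 6 genes were added and 14 dropped where the file's description or the reference position contradicted the list, or a gene was found under another identifier. Lists with at least 5 tested members, 21 of them, were compared with all other genes by camera with a preset correlation of 0.01 and with an estimated correlation, and were tested by fry (limma 3.58.1), adjusted over the lists. Fry gave adjusted p-values under the threshold for 15 lists in a common direction and for 21 in either direction, and does not compare a list with other genes. No list passed camera with an estimated correlation, the adjusted p-values running from 0.447 to 0.982. GO and KEGG terms with 10 to 500 tested members were tested with a one-sided Fisher's exact test against the 16507 tested genes that carry any term. Changed genes were also counted in windows of 50 neighbouring tested genes and compared with 10000 shuffles of the calls.

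Genes named in the text follow a rule fixed beforehand, which took 113 genes, and the text gives examples from each part. It takes the 2 targeted NAC genes, the 10 largest rises and 10 largest falls among called genes with no overlap between lines, at least 5 CPM in the higher line and a description, up to 4 members of each list with the smallest adjusted p, and the bt2, sh2, 16-kDa gamma-zein, 27-kDa gamma-zein, opaque2 and pbf1 genes. Descriptions that call a protein uncharacterized, hypothetical or unknown were read as no description, a reading chosen after seeing the data. The identities of NAC128, NAC130, bt2, sh2 and the gamma-zein genes rest on their known identifiers, since the files describe them in other words.

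Alternatives fixed before the data were examined were DESeq2 size factors, library totals and TMM without zein genes as scaling, no filter and at least 1 CPM in 3 samples as filters, the DESeq2 1.42.0 Wald test, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, a 2-fold minimum, an adjusted p under 0.01, and leaving out each library in turn. Chosen after seeing the data were the lists as first written and the removal of a length trend. For the latter a loess curve (span 0.3) of log2 CPM against relative gene length, taken from the ratio of counts to FPKM and available for 99.6% of tested genes, was removed in each library as an offset.

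The steps were tested on simulated data. Counts for the 22259 genes were drawn from the real means and library sizes with 200 changed genes, and edgeR called 53 of 100 genes with a log2 fold change of 1 and 84 of 100 with a log2 fold change of 2, with 15 false among 152 calls (9.9%, above the nominal 5%). The false share was 28.2% for DESeq2, 17.1% for edgeR with the replicate block and 11.3% for limma. With 200 changed genes the adjustment is stricter than with the 10519 genes called in the real comparison, so these shares need not hold there. The term test recovered 5 of 5 implanted terms and gave 0 terms for random genes. The window test found an implanted segment (p = 0.001 by permutation) and gave p-values under 0.05 in 3 of 40 simulations without a segment. A simulated length slope of 0.099 went to 0 after removal.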

Results

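The series compared developing maize endosperm, the starch- and protein-storing tissue of the kernel, between the inbred line B73 and nacRNAi, a transgenic sibling line in the B73 background that carries an RNA interference construct. RNA interference lowers the transcripts of genes that match the construct. All libraries came from kernels at 20 days after pollination, with 3 libraries from wild type and 3 from nacRNAi. Gene-level read counts totalled 64603196, 59596459 and 55812999 in the wild-type libraries and 69670876, 60466236 and 59084750 in the nacRNAi libraries. The 10 most abundant genes took 35.2% to 36.9% of the counts in wild type and at most 25.9% in nacRNAi. The first principal component of the log2 CPM values carried 67.9% of the variance and placed the lines apart, with wild type at -88.2 to -83.5 and nacRNAi at 84.1 to 86.2. Nothing in the labels says that libraries of a line came from separate plants or ears, so the p-values measure only the spread between these samples, which may be technical.

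The first question was whether the construct's targets were lowered. The targets were taken as the endosperm NAC transcription factors NAC128 and NAC130 from knowledge of the study, since the labels say only that NAC genes were targeted. NAC130 (Zm00001d008403, chromosome 8, 7619712 to 7621282) fell 5.42-fold, from 1242 ± 162 CPM in wild type (SD, n = 3) to 229 ± 8.21 CPM in nacRNAi (SD, n = 3), and its values in the libraries were 1337, 1335 and 1055 CPM against 238, 227 and 222 CPM. Its log2 fold change was -2.44 (SE 0.10, edgeR adjusted p = 4.22e-06), and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. NAC128 (Zm00001d040189, chromosome 3, 31401124 to 31403248) stood at 309, 359 and 272 CPM in wild type and at 248, 300 and 284 CPM in nacRNAi. Its log2 fold change of -0.18 (SE 0.11) did not pass the test (edgeR adjusted p = 0.245, exact two-sided permutation p = 0.4), and adjusted over the list alone 1 of the 2 genes passed. Without wild-type replicate 3 both passed over the list alone, as lower, though NAC128 did not pass over all genes. Scaled by library totals NAC128 was higher in nacRNAi, with a log2 fold change of 0.35 (edgeR adjusted p = 0.0168), and on log2(FPKM + 1) the value was 0.54 (limma adjusted p = 0.00348).

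**Figure D1:**
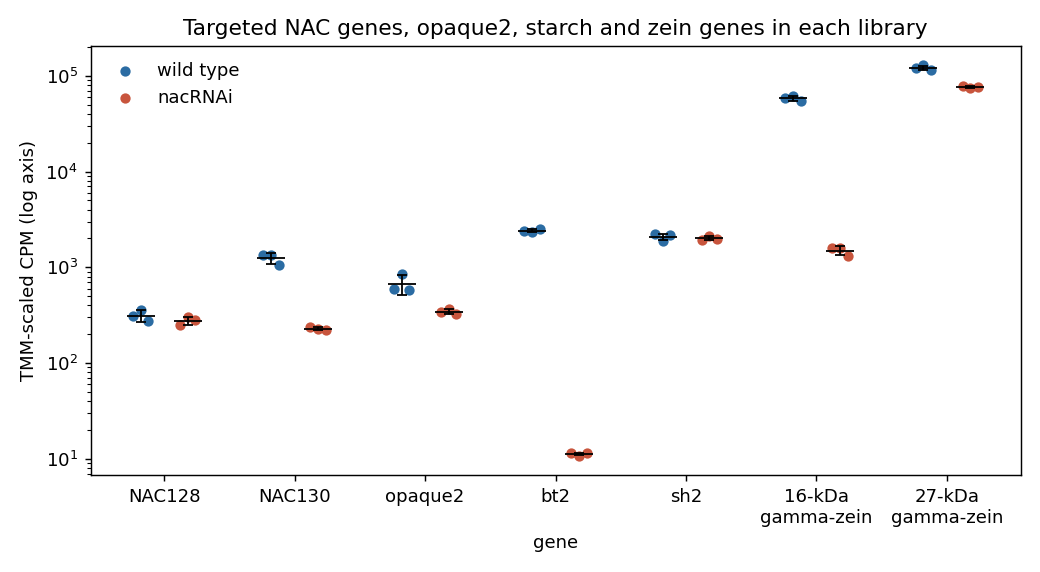
TMM-scaled CPM on a log axis for 7 genes, with 1 point per library, a horizontal bar at the mean and error bars of 1 SD (n = 3 per line). NAC130, bt2 and the 16-kDa gamma-zein gene lie far lower in nacRNAi, at means of 229, 11.2 and 1494 CPM, while NAC128 and sh2 overlap between the lines under this scaling.

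Across the transcriptome the lines differed widely. Of 22259 genes tested, 10519 (47.3%) changed, 5171 higher and 5348 lower in nacRNAi (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 3926 of them changed at least 2-fold. Of all 22259 genes 13174 (59.2%) had no overlap between the lines' libraries, where chance gives 10%. These changes are relative to the median gene. With library totals in place of TMM factors the median gene rose by 0.52 log2, 13238 genes passed and 84.9% of them were higher, against 49.2% with TMM. On log2(FPKM + 1) and log2(FPKM + 0.1) the median shifts were 0.38 and 0.59, and 89.2% of the genes called by limma were higher. Of the 10519 genes called with TMM, 7520 also passed under library totals, 345 of them with the opposite sign. On log2(FPKM + 1) 7529 of them also passed, 1004 with the opposite sign. Counts alone cannot say which scale reflects RNA per kernel.

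Zein genes, which encode the prolamin storage proteins of the endosperm, fell under every scaling tried. Of 20 tested members 19 fell and none rose, with a median log2 fold change of -1.42, and 19 passed adjusted over the list alone. Under library totals 15 fell and none rose, with a median of -0.88. The 16-kDa gamma-zein gene (Zm00001d005793, chromosome 2, 188849023 to 188849574, described as Zein-beta in the files) fell 38.8-fold, from 57900 ± 3445 to 1494 ± 166 CPM (log2 fold change -5.28, SE 0.13, edgeR adjusted p = 5.39e-07). The 50-kDa gamma-zein gene fell from 17140 ± 727 to 3256 ± 91.2 CPM (log2 fold change -2.40), Zein-alpha 19D1 from 4846 ± 233 to 835 ± 90.7 CPM (-2.54) and the 18-kDa delta-zein gene from 6764 ± 524 to 1972 ± 258 CPM (-1.78). The 27-kDa gamma-zein gene (Zm00001d020592, described as Glutelin-2), the most abundant transcript, moved far less, from 120800 ± 6732 to 76080 ± 2325 CPM (log2 fold change -0.67, edgeR adjusted p = 0.000583). Its call ended under library totals, at -0.15 (edgeR adjusted p = 0.166), and on log2(FPKM + 1), at 0.00 (limma adjusted p = 1). The member that did not pass was 22kD alpha zein5 (Zm00001d048806), named after its value was seen, at -1.40 (edgeR adjusted p = 0.15). Zein genes together took 38.9% ± 1.34 of all counts in wild type and 23.2% ± 0.49 in nacRNAi (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). The shares were 28.8% and 14.1% with the list as first written, which lacked the 27-kDa gamma-zein gene. The 95% Wilson interval of the share in wild-type replicate 2, 39.54% to 39.57%, shows that the spread between libraries, not the depth, sets the error. Against all other genes the list passed camera with a preset correlation (adjusted p = 3.22e-25) but not with an estimated correlation (adjusted p = 0.447). Fry, which asks whether the members move in a common direction, gave an adjusted p of 0.000917. Reads of near-identical alpha-zein copies can be divided between paralogs, so values of single alpha-zein genes are uncertain, and Zein-alpha A20 (Zm00001d019155) overlaps another gene model.

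Starch synthesis genes changed in both directions, with the largest change in the whole list at bt2. The bt2 gene (Zm00001d050032, chromosome 4, 61315575 to 61321350), which encodes the small subunit of the endosperm ADP-glucose pyrophosphorylase, fell 215-fold, from 2416 ± 97.4 to 11.2 ± 0.392 CPM (log2 fold change -7.75, SE 0.09, edgeR adjusted p = 1.05e-08). The gene of the large subunit, sh2 (Zm00001d044129), was at 2084 ± 168 and 2010 ± 87.4 CPM, with a log2 fold change of -0.05 that did not pass (edgeR adjusted p = 0.626) and that was 0.46 under library totals (edgeR adjusted p = 0.0031) and -0.28 with the length trend removed (edgeR adjusted p = 0.0184). Starch synthase I fell from 418 ± 32.2 to 159 ± 18.1 CPM (-1.40), Sugary2, a starch synthase, from 179 ± 7.09 to 75.3 ± 6.07 CPM (-1.25), and the starch branching enzyme gene Zm00001d016684 from 1039 ± 81.3 to 481 ± 33.7 CPM (-1.11). Of 35 tested members 9 rose and 11 fell, 22 passed adjusted over the list alone, and 8 changed at least 2-fold. The median was -0.02 and turned to 0.49 under library totals, where 19 members were higher and 6 lower. The list did not pass camera (adjusted p = 0.0575, and 0.528 with an estimated correlation). It passed when wild-type replicate 2 was left out (adjusted p = 0.034, but 0.389 with an estimated correlation). It also passed with the gene-length trend given for the ribosomal protein genes removed (adjusted p = 0.000917, but 0.391 with an estimated correlation). With DESeq2 it passed downward (camera adjusted p = 0.000981), although 11 members were higher and 10 lower and the median was 0.03. An estimated correlation was not used in that setting.

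Genes of sugar supply and sugar signalling went both ways relative to the median gene, and mostly up under library totals. Changed genes in general also went up in that setting, where 84.9% of them were higher and the median gene rose by 0.52 log2. Among 21 tested sucrose breakdown genes 6 rose and 4 fell, and 10 passed adjusted over the list alone. With 1 library left out 5 to 12 changed. Sucrose synthase 1 rose from 7062 ± 1581 to 12400 ± 600 CPM (log2 fold change 0.81, edgeR adjusted p = 0.00356), a gene described as an invertase (Zm00001d028111) rose by 1.51, and the alkaline/neutral invertase CINV2 fell by 2.32 on the log2 scale. The median of this list was -0.01 but 0.50 under library totals, where 13 members were higher and 1 lower, its mean 0.07 and its camera direction upward (adjusted p = 0.659). Of 40 trehalose and sugar signalling genes 12 rose and 8 fell, with 20 passing adjusted over the list alone (camera adjusted p = 0.335). Of these genes 20 were higher and 1 lower under library totals (median 0.53) and 30 and 1 on log2(FPKM + 1). The trehalose-6-phosphate phosphatase genes 10 and 9 rose by 3.06 and 2.69 on the log2 scale, trehalose-6-phosphate synthase2 rose by 1.16, and a regulatory subunit of the SNF1-related protein kinase fell by 1.83. Of 38 sugar transporter genes 12 rose and 4 fell, and 15 passed adjusted over the list alone (median 0.16, camera adjusted p = 0.11), with 22 higher and 2 lower under library totals (median 0.68). An ERD6-like transporter (Zm00001d039052) rose from 0.184 ± 0.0875 to 12.1 ± 0.186 CPM (6.01) and Sugar transport protein 7 fell from 47.2 ± 2.77 to 20.2 ± 1.69 CPM (-1.22).

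Among the regulators of storage genes, opaque2, a bZIP activator of zein genes (Zm00001d018971), fell from 672 ± 153 to 344 ± 21.0 CPM (log2 fold change -0.96, edgeR adjusted p = 0.00229). Viviparous-1, a regulator of seed maturation, fell by 0.76 on the log2 scale (edgeR adjusted p = 0.00411), a call lost under library totals, at -0.24 (edgeR adjusted p = 0.24), and on log2(FPKM + 1), at -0.19 (limma adjusted p = 0.195). The other members of this list of 5 did not pass, among them Opaque2 heterodimerizing protein 1 at -0.38 (0.13 under library totals) and naked endosperm1 at 0.03. The latter was higher under library totals (0.55, edgeR adjusted p = 0.00177) and on log2(FPKM + 1) (0.61, limma adjusted p = 0.00237). Adjusted over the list alone 2 passed, and the median was -0.38, or 0.13 under library totals (camera adjusted p = 0.468). The prolamin-box binding factor gene pbf1 was not matched to an ID here. In the wider NAC family 21 of 58 tested genes rose and 15 fell, and 37 passed adjusted over the list alone, while 31 were higher and 12 lower under library totals. NAC domain-containing protein 21/22 rose by 4.19, the SNAC1-type gene Zm00001d034601 rose from 14.7 ± 1.39 to 40.4 ± 1.10 CPM (1.46), NAC domain containing protein 84 fell by 2.82 and Zm00001d011555 fell by 3.70. The median of this list was 0.31 while its mean was -0.32 and its camera direction downward (adjusted p = 0.979).

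ER chaperone and protein folding genes, which serve storage protein folding, changed in 16 of 28 cases, 7 higher and 9 lower, and 16 passed adjusted over the list alone (median -0.07, or 0.45 under library totals with 19 higher and 4 lower; camera adjusted p = 0.659). Calreticulin-2 fell from 84.8 ± 3.45 to 31.6 ± 4.61 CPM (-1.42), protein disulfide isomerase8 from 131 ± 6.18 to 57.7 ± 2.93 CPM (-1.18), and Endoplasmic oxidoreductin-1 rose from 67.2 ± 7.99 to 147 ± 0.768 CPM (1.13). Of 8 globulin and other storage protein genes 3 fell, 3 adjusted over the list alone (median -0.42, or 0.10 under library totals; camera adjusted p = 0.659). With 1 library left out 1 to 4 changed, and with DESeq2 5. A vicilin-like gene (Zm00001d048176) fell by 1.06 on the log2 scale. The falls of globulin3 (-0.63, edgeR adjusted p = 0.0368) and of a legumin-like gene (-0.47, edgeR adjusted p = 0.0248) were lost when single libraries were left out and with the length trend removed. That of globulin3 (Zm00001d038597) was also lost without a filter. Under library totals both calls were lost, with globulin3 at -0.12 (edgeR adjusted p = 0.607) and the legumin-like gene (Zm00001d011036) at 0.04 (edgeR adjusted p = 0.833). Globulin-1 (Zm00001d033447) stood at 0.52 (edgeR adjusted p = 0.0596). It passed as higher under library totals (1.04, edgeR adjusted p = 0.00115), on log2(FPKM + 1) (1.02, limma adjusted p = 0.00625), with DESeq2 (0.52, adjusted p = 0.00661), without wild-type replicate 2 (0.75, edgeR adjusted p = 0.000832) and with the length trend removed (0.64, edgeR adjusted p = 0.0275).

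Embryo and oil body genes, a list meant to mark embryo and aleurone, were expressed enough to be tested in 41 of 108 cases, and of these 25 fell and 3 rose. Adjusted over the list alone 29 passed. The median was -0.64, and it was -0.12 under library totals, with 6 higher and 11 lower, and turned to 0.18 on log2(FPKM + 1), with 9 higher and 6 lower. A caleosin gene fell from 88.9 ± 2.80 to 36.5 ± 1.55 CPM (-1.28), and Oleosin Zm-I from 685 ± 39.2 to 375 ± 30.3 CPM (-0.87), the last at 0.12 on log2(FPKM + 1) (limma adjusted p = 0.384). Zm00001d021289, described as of the late embryogenesis abundant (LEA) hydroxyproline-rich glycoprotein family, fell from 236 ± 27.5 to 49.5 ± 7.09 CPM (-2.25). That description alone does not make it an embryo marker. Camera gave an adjusted p of 0.00109, and of 0.528 with an estimated correlation. Camera also passed downward under library totals (adjusted p = 0.000505) and on log2(FPKM + 1) (0.0194), but not with an estimated correlation (0.627 and 0.671). Library totals move all genes up together, and camera compares a list with the other genes. Its pass there is therefore no check on the scaling. Markers of other kernel parts were few. Of 3 aleurone genes 2 fell, 2 adjusted over the list alone. These were Supernumerary aleurone1 at -0.29 and aleurone9 at -0.21, whose calls were lost without single libraries. Both passed as higher under library totals, at 0.23 and 0.31 (edgeR adjusted p = 0.037 and 0.0103), where the list median of -0.21 became 0.31. On log2(FPKM + 1) both also passed as higher, at 0.31 each (limma adjusted p = 0.0335 and 0.00886). With the length trend removed Supernumerary aleurone1 (Zm00001d046599) was at 0.00 (edgeR adjusted p = 0.993), and the call of aleurone9 was also lost with DESeq2, without a filter and with the replicate block. The third (Zm00001d021140), at 0.12, passed as higher under library totals (0.63, edgeR adjusted p = 0.00295). Of 3 basal transfer layer genes 0 passed with edgeR in the main comparison, the list alone and unadjusted p-values (0.109, 0.407 and 0.795) giving 0 as well. Without nacRNAi replicate 1 the median of these genes was -3.25 and 1 passed as lower, the BETL3 gene (Zm00001d041671) at -4.19 (edgeR adjusted p = 0.0309). Basal endosperm transfer layer9 ranged from 0.708 to 8.05 CPM in wild type and from 0.488 to 9.67 CPM in nacRNAi. None of the 7 embryo surrounding region genes was expressed enough to be tested. Of 25 photosynthesis genes 5 rose and 9 fell, 14 adjusted over the list alone, with 8 changed under the filter of 1 CPM (median -0.07, or 0.43 under library totals; camera adjusted p = 0.587, and 0.0194 downward on log2(FPKM + 1), where it was 0.38 with an estimated correlation). Under library totals 9 were higher and 7 lower, and on log2(FPKM + 1) 11 and 7. Photosystem I reaction center subunit V fell from 3.02 ± 0.102 to 0.135 ± 0.0434 CPM (-4.48), and Chlorophyll a-b binding protein 6 rose from 0.188 ± 0.0385 to 3.90 ± 1.28 CPM (4.37).

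Ribosomal protein genes fell relative to the median gene, but under library totals 67 rose and 57 fell, and on log2(FPKM + 1) the list median turned positive. Of 314 tested members 202 fell and 14 rose, with 226 passing adjusted over the list alone, and the median log2 fold change was -0.54. The gene of 60S ribosomal protein L39 (Zm00001d052025) fell from 120 ± 1.89 to 59.0 ± 0.373 CPM (-1.02, edgeR adjusted p = 9.12e-06), that of 60S ribosomal protein L35 (Zm00001d004052) from 209 ± 2.39 to 103 ± 4.71 CPM (-1.03), and that of 40S ribosomal protein S30 (Zm00001d018410) from 127 ± 0.919 to 66.1 ± 0.769 CPM (-0.95, but -0.14 on log2(FPKM + 1), limma adjusted p = 0.111). Camera gave an adjusted p of 3.61e-13 with the preset correlation and of 0.496 with an estimated correlation. The median was -0.03 under library totals and 0.17 on log2(FPKM + 1), where 118 members were higher and 20 lower. Against other genes camera passed downward on these scales (adjusted p = 3.8e-05 and 0.0194), but not with an estimated correlation (0.634 and 0.671). Since library totals move all genes up together, the pass there is no check on the scaling. Fold changes also followed gene length. The median log2 fold change rose from -0.34 in the shortest of 10 equal groups of genes to 0.29 in the longest, and log2 CPM per doubling of length had slopes of -0.043, -0.124 and -0.072 in the wild-type libraries and 0.045, 0.084 and 0.110 in the nacRNAi libraries. Per doubling of the span between start and end positions the slopes were smaller, at -0.013, -0.079 and -0.041 in wild type and 0.019, 0.05 and 0.065 in nacRNAi. The slopes differ in sign between the lines, so a difference in RNA quality or library preparation, of which the labels say nothing, would be confounded with line. With this trend removed from each library, a setting chosen after seeing the data, the ribosomal median was -0.33, with 172 members lower and 19 higher (camera adjusted p = 2.44e-05, but 0.578 with an estimated correlation), and 9799 genes changed in all, of which 8470 were among the 10519.

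**Figure D2:**
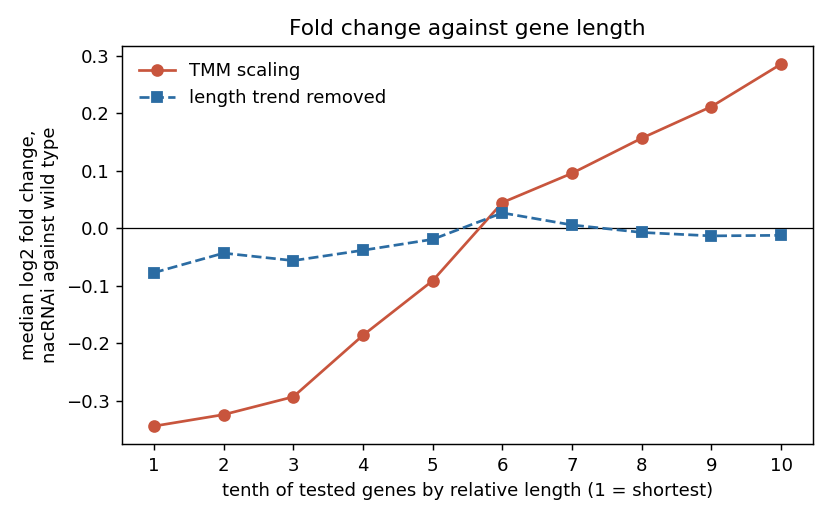
Median log2 fold change, nacRNAi against wild type, in each of 10 equal groups of tested genes ordered by relative length, from shortest to longest. With TMM scaling the medians climb from -0.34 to 0.29, and with the length trend of each library removed they lie between -0.08 and 0.03.

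Defense and protease inhibitor genes fell in 50 of 113 cases and rose in 23, with 75 passing adjusted over the list alone and a median of -0.59, which was -0.06 under library totals and 0.12 on log2(FPKM + 1). On these scales 29 were higher and 31 lower, and 42 higher and 22 lower. The subtilisin-chymotrypsin inhibitor CI-1B gene fell from 1324 ± 103 to 132 ± 14.6 CPM (-3.33, edgeR adjusted p = 1.52e-06), Peroxidase 17 from 64.8 ± 4.43 to 5.61 ± 0.856 CPM (-3.53), and kunitz trypsin inhibitor 1 from 14.2 ± 1.97 to 0.0541 ± 0.0579 CPM (-7.91). Camera passed (adjusted p = 0.0113) but not with an estimated correlation (adjusted p = 0.528), with DESeq2 (0.0914), without a filter on low counts (0.0678) or with the length trend removed (0.134). Under library totals and on log2(FPKM + 1) camera passed downward (adjusted p = 6.16e-05 and 2.69e-05), but not with an estimated correlation (0.291 and 0.226). The pass under library totals is again no check on the scaling. Heat shock genes, a list fixed as cytosolic whose patterns also took in genes described as chloroplastic or mitochondrial, rose in 25 of 70 cases and fell in 11, 37 passing adjusted over the list alone (median 0.28). Heat stress transcription factor A-6b rose from 15.9 ± 0.315 to 59.7 ± 5.20 CPM (1.91). Of a pair of genes both described as a chloroplastic 70-kDa heat shock protein, Zm00001d033591 rose by 1.10 and Zm00001d023802 fell by 1.22 on the log2 scale. The list did not pass camera (adjusted p = 0.0575). It did under library totals (adjusted p = 0.02), with 48 members higher and 5 lower, with the replicate block (0.0359), without wild-type replicate 2 (0.0476) and without nacRNAi replicate 1 (0.0248), but in none of these with an estimated correlation (0.634, 0.75, 0.407 and 0.736). Of 59 programmed cell death and protease genes 14 rose and 13 fell, 27 adjusted over the list alone (median -0.12, or 0.40 under library totals with 27 higher and 6 lower; camera adjusted p = 0.67). Endonuclease 1 fell from 46.8 ± 13.4 to 0.340 ± 0.177 CPM (-7.07), Aspartic proteinase A1 from 323 ± 5.13 to 119 ± 7.56 CPM (-1.44), and the beta-isozyme of vacuolar processing enzyme from 195 ± 18.3 to 73.4 ± 4.66 CPM (-1.41).

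Hormone genes went both ways. Of 117 abscisic acid genes 35 rose and 35 fell, 71 adjusted over the list alone, with a median of 0.08, a mean of -0.08 and a downward camera direction (adjusted p = 0.979). Under library totals 60 were higher and 14 lower (median 0.59), and on log2(FPKM + 1) 70 and 8. The receptor genes PYL9 (Zm00001d037719) and PYL5 fell, from 230 ± 15.1 to 62.7 ± 0.600 CPM (-1.87) and from 68.6 ± 3.96 to 15.4 ± 1.11 CPM (-2.15), while Protein phosphatase 2C 16 rose from 3.90 ± 0.624 to 21.1 ± 1.38 CPM (2.43). Of 84 auxin genes 10 rose and 30 fell, 40 adjusted over the list alone (median -0.14, or 0.37 under library totals with 30 higher and 16 lower). Camera gave an adjusted p of 0.186, of 0.0407 under library totals and of 0.0194 on log2(FPKM + 1), each downward, the last 2 becoming 0.634 and 0.671 with an estimated correlation. Indole-3-acetic acid-amido synthetase GH3.6, an enzyme that conjugates auxin, fell from 125 ± 10.5 to 31.6 ± 2.05 CPM (-1.99), and a gene described as Auxin response factor 3 (Zm00001d012731) fell by 2.62 on the log2 scale.

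In the remaining lists camera found no shift against other genes in the main comparison. Of 44 amino acid metabolism genes 11 rose and 12 fell, 24 adjusted over the list alone (median 0.09, camera adjusted p = 0.817). Of these genes 25 were higher and 6 lower under library totals (median 0.60) and 23 and 4 on log2(FPKM + 1). The gene of lysine-ketoglutarate reductase/saccharopine dehydrogenase1, which degrades lysine, fell from 554 ± 38.0 to 260 ± 2.00 CPM (-1.09), and Aspartokinase (Zm00001d034851) rose by 1.80. Of 48 lipid synthesis genes 9 rose and 18 fell, 27 adjusted over the list alone (median -0.24, or 0.27 under library totals with 18 higher and 6 lower; camera adjusted p = 0.397). Acetyl-CoA carboxylase 1 and acetyl-CoA carboxylase2 both rose by 0.91, while the thioesterase gene ATL3 fell by 5.82. Of 138 cell cycle and histone genes 17 rose and 41 fell, 57 adjusted over the list alone (median -0.28, 0.24 under library totals with 45 higher and 16 lower, and -0.09 with the length trend removed). Camera gave an adjusted p of 0.186, and of 0.0215 without wild-type replicate 1, where it was 0.675 with an estimated correlation. Without wild-type replicate 3 the median was -0.06, with 21 higher and 37 lower (camera adjusted p = 0.464). Cyclin-dependent kinase inhibitor 5 fell by 1.56 and a Histone H3 gene (Zm00001d029394) by 0.96 on the log2 scale. Of 32 RNA silencing genes 12 rose and 2 fell, 14 adjusted over the list alone (median 0.27, camera adjusted p = 0.317). Under library totals 19 were higher and 2 lower (median 0.79), and with the length trend removed 10 and 6 (median 0.05). Argonaute108 fell from 35.6 ± 1.80 to 7.35 ± 0.275 CPM (-2.27), and argonaute1c rose from 26.8 ± 1.01 to 49.4 ± 3.28 CPM (0.88).

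**Figure D3:**
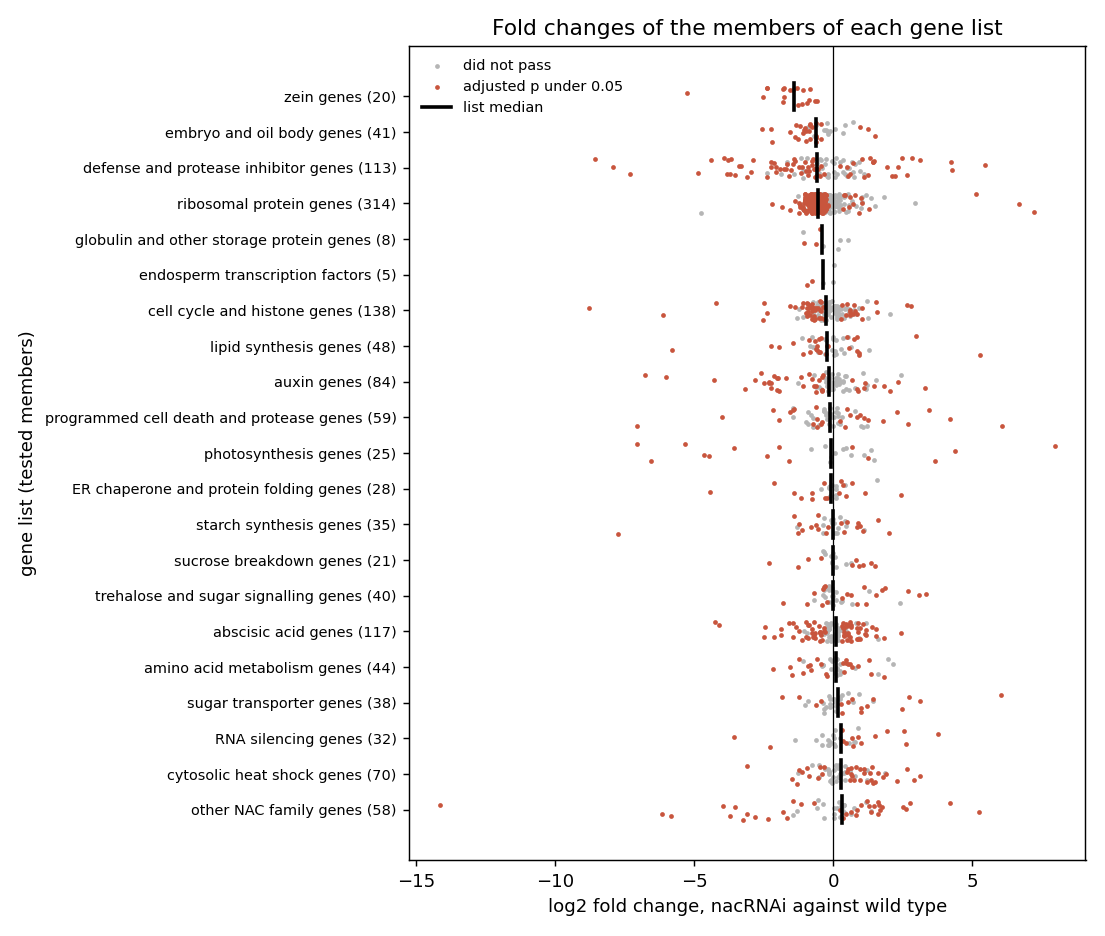
Log2 fold change, nacRNAi against wild type, of every tested member of the 21 gene lists with at least 5 tested members (1 point per gene, coloured where adjusted p was under 0.05), with a bar at the list median and the number of tested members after each name. Zein genes lie lowest as a list, at a median of -1.42; 11 of the medians of all lists turned positive under library totals.

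The largest single changes reached genes that were nearly absent in either line. Among genes with a description, no overlap between the lines and at least 5 CPM in the higher line, the largest rises were those of a SCARECROW gene (Zm00001d003657, log2 fold change 9.70), safener induced1 (9.29, from 0.174 ± 0.0669 to 110 ± 20.8 CPM), Cinnamoyl-CoA reductase 1 (8.95), the urea transporter gene DUR3 (8.22), Vegetative storage protein 2 (6.46), a gene described as post-illumination chlorophyll fluorescence increase (6.23), a WAT1-related gene (6.21), the ERD6-like transporter above, a homeobox leucine zipper gene (5.88) and PLASMODESMATA CALLOSE-BINDING PROTEIN 5 (5.56). The 10 genes with the lowest fitted log2 fold changes under the same limits included Zm00001d039004, described as a NAC87-type factor, at 36.1 ± 8.40 CPM in wild type and 0 counts in all 3 nacRNAi libraries, which is at least 902-fold lower with 3 counts per library taken as the floor, a bound that covers counting error only and that does not set its rank. The others were bHLH76 (-11.33), gibberellin 2-oxidase1 (-10.84, from 117 ± 21.4 to 0.0645 ± 0.0460 CPM), a PHD finger gene described as MALE STERILITY 1 (-10.42), Lysine histidine transporter-like 7 (-9.94), Ribonuclease 1 (-9.46, from 255 ± 33.2 to 0.364 ± 0.118 CPM), monooxygenase 1 (-9.18), Actin-depolymerizing factor 10 (-8.34), DUF679 domain membrane protein 7 (-8.21) and DOF1.2 (-8.03). Passing edgeR's test was a condition for entering these rankings, and the largest adjusted p was 0.000531. Ranks of genes near 0 counts in a line are not firm, since their fold rests on values under the floor of 3 counts. SCARECROW stood at 0, 0.0208 and 0 CPM in wild type. The bHLH76, MALE STERILITY 1 and Lysine histidine transporter-like 7 genes were at 0 in all but 1 nacRNAi library.

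Annotation terms were tested among all changed genes. Of 1620 GO and KEGG terms tested 38 were enriched (one-sided Fisher's exact test, Benjamini-Hochberg), 18 among higher and 20 among lower genes. Of the 266 tested members of the KEGG ribosome pathway 203 fell (adjusted p = 8.42e-68), of 56 genes of nutrient reservoir activity 38 fell (adjusted p = 2.75e-09), of 90 oxidative phosphorylation genes 45 fell (adjusted p = 3.11e-05), and of 44 genes of mitochondrial complex I 27 fell (adjusted p = 3.96e-05). Among higher genes the terms included nucleoplasm with 114 of 323, trans-Golgi network with 104 of 298, RNA secondary structure unwinding with 38 of 84 and glycolysis/gluconeogenesis with 37 of 88 (adjusted p = 0.0155). When only genes with an adjusted p under 0.01 were taken, nucleoplasm and trans-Golgi network were no longer enriched (adjusted p = 0.207 and 0.133). With the length trend removed 15 terms were enriched, 13 of them among the 38, and none was enriched among higher genes in this setting. Fisher's exact test treats genes as independent, while camera estimated correlations of 0.0952 among ribosomal protein genes and 0.476 among zein genes. Terms were not tested on the calls under library totals or on the FPKM scales, so these rises and falls are relative to the median gene.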

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

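The length-trend removal and the lists as first written were chosen after seeing the data, and all other settings were fixed before. The zein count stayed at 14 to 19 members, all of them lower, in the planned settings, and the share of counts in zein genes was lower in nacRNAi in all settings run, by 14.8 to 20.3 percentage points. The count of changed genes was 8525 to 9714 with 1 library left out, 9742 to 11049 with other filters, DESeq2 or DESeq2 size factors, 6992 at an adjusted p under 0.01 and 3926 with at least a 2-fold change, where 8 starch synthesis genes remained. With the length trend removed 15 annotation terms were enriched. Both targeted NAC genes passed, so 2 in place of 1, under library totals and on either FPKM scale, NAC128 then being higher, and both passed as lower over the list alone without wild_type replicate 3.

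Library totals turned the sign of Zm00001d040189 (NAC128) to 0.35, Zm00001d034457 (Opaque2 heterodimerizing protein 1) to 0.13, Zm00001d011036 (legumin-like) to 0.04, Zm00001d041822 (basal endosperm transfer layer9) to 0.11, Zm00001d046599 (Supernumerary aleurone1) to 0.23, Zm00001d012571 (aleurone9) to 0.31 and Zm00001d044129 (sh2) to 0.46. With limma on log2(FPKM + 1) and on log2(FPKM + 0.1) the values were 0.54 and 0.55 for Zm00001d040189, 0.12 and 0.19 for Zm00001d034457, 0.16 and 0.17 for Zm00001d011036, 0.41 and 0.41 for Zm00001d038597 (globulin3), 0.12 and 0.12 for Zm00001d002768 (Oleosin Zm-I), 0.31 and 0.31 for Zm00001d046599, 0.31 and 0.38 for Zm00001d012571, and 0.38 and 0.38 for Zm00001d044129. Library totals lack the factors that set the median gene to 0, which moves all genes up by construction, and the cause on the FPKM scales was not tested. With the length trend removed Zm00001d002654 (naked endosperm1) was at -0.01 and Zm00001d021140 (an aleurone morphogenesis gene) at -0.08, and the cause was not tested. Without single libraries Zm00001d002654 ranged from -0.02 to 0.10. Zm00001d042231 (basal endosperm transfer layer10) was at -2.06 without nacRNAi replicate 1 and 0.22 without wild_type replicate 1, and Zm00001d041822 at -3.25 and 0.26, all without a call, while Zm00001d041671 (BETL3) gained one without nacRNAi replicate 1 (-4.19).

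Of the 10519 genes called in the main comparison, 8335 to 9048 were also called with 1 library left out, which leaves fewer samples. Most named genes were chosen for a small adjusted p or a large change in these data, so their calls were likely to be kept. Of the 104 named genes that passed, 4 lost the call without at least 1 library. Zm00001d012571 lost it without any of the 6, Zm00001d038597 without any but nacRNAi replicate 2, Zm00001d046599 without wild-type replicate 2 or nacRNAi replicate 2 or 3, and Zm00001d011036 without wild-type replicate 3 or nacRNAi replicate 2 or 3. With the replicate block 9273 genes changed, 9037 of them also changed without the block. Replicate numbers did not pair the samples, as same-numbered libraries had deviations that correlated across genes at 0.011, -0.049 and -0.103, and no wild-type library correlated best with its own number. At these depths the simulated 2-fold changes were called in 53 of 100 cases, so a gene that did not pass is not shown to be unchanged.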

Other observations

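The genes and gene groups in this and the next paragraph were chosen after their values were seen. Genes whose descriptions begin with opaque or floury, which takes in Opaque2 heterodimerizing protein 1 and leaves out opaque2, given in the report, fell in 5 of 8 cases and rose in none, with a median log2 fold change of -1.46 that was -0.94 under library totals. Opaque endosperm1, which encodes a myosin, fell from 88.3 ± 5.17 to 25.2 ± 0.825 CPM (log2 fold change -1.81, edgeR adjusted p = 2.63e-06), floury endosperm1, a protein body membrane protein gene, from 121 ± 6.87 to 41.9 ± 2.29 CPM (-1.52), and opaque endosperm10 from 247 ± 75.6 to 57.7 ± 5.07 CPM (-2.10). The others that fell, floury2 and floury4, are zein genes, at -2.40 and -1.39. Abscisic acid 8'-hydroxylase genes, whose enzymes break the hormone down, fell in 3 of 5 cases, hydroxylase3 from 271 ± 40.2 to 15.8 ± 5.07 CPM (-4.10) and hydroxylase2 from 3.41 ± 2.30 to 0.176 ± 0.0313 CPM (-4.26), while hydroxylase1 was at 1.60 without a call (edgeR adjusted p = 0.113). Of 7 gibberellin enzyme genes 3 fell and 1 rose, with a median of -0.27 that was 0.23 under library totals, and Gibberellin 20 oxidase 2 fell from 15.7 ± 1.13 to 1.81 ± 0.168 CPM (-3.11).

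In raw shares of counts, which amount to scaling by library totals, the 27-kDa gamma-zein gene held 10.1% in wild type and 9.10% in nacRNAi, the 15-kDa zein gene 6.44% and 4.83%, and the 16-kDa gamma-zein gene 4.83% and 0.18% (means of 3 libraries). Sucrose synthase 1 went from 0.59% to 1.48%, and the trypsin inhibitor gene corn-activated Hageman factor inhibitor1 from 1.29% to 2.07%, although its TMM-scaled log2 fold change of 0.16 did not pass (edgeR adjusted p = 0.13).

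The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The division by line gave 10519 changed genes, and the highest other gave 0. For zein genes the values were 19 and 0, for starch synthesis genes 20 and 0, and for annotation terms 38 and 0, so that 1 of the 10 divisions reached each real value. Every other division mixes the lines, which puts the line difference into the spread within each side. Low counts there were therefore built in and say little about chance. Camera with the preset correlation called 4 lists for the real division and up to 8 for another, and 6 of the 10 divisions gave at least 4. Changed genes made up 40.4% of tested genes on chromosome 3 and 45.4% to 50.5% on the others, and the cause was not tested. The fullest window of 50 neighbouring tested genes held 76.0% changed genes (p = 0.1346 by permutation), and windows of 25 and of 100 genes held 84.0% (p = 0.6861) and 67.0% (p = 0.1187).

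The tests of the patterns that follow were chosen after the results were seen, except that of genotype segments. Ribosomal protein genes fell by 0.54 log2 in the median, in a comparison in which short genes fell in general. Length as the whole cause is argued against by the median of -0.33 with the length trend removed, where 172 members were lower and 19 higher, though the smaller value is consistent with length accounting for part of the fall and the camera call in that setting (adjusted p = 2.44e-05) was lost with an estimated correlation (0.578). A few abundant genes taking the counts cannot be told apart from other causes, because leaving zein genes out of totals and factors moved neither the median gene nor the list (-0.54). Whether RNA per kernel changed cannot be read from these counts, and an effect of the construct stays open, untested.

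NAC128 stood near its wild-type level while NAC130 fell 5.42-fold. A fall hidden by scaling cannot be told apart from no fall, because DESeq2 size factors and TMM without zein genes gave about the same value as TMM, the lowest being -0.18, and library totals move all genes up. Reads from the construct itself, which may carry part of the gene, could raise the NAC128 count in nacRNAi and hide a fall of the native transcript. The value of -0.18 cannot be told apart from that case, because reads by position along the gene were not analysed here. A construct that acts mainly on NAC130 at this stage is the biological alternative and was not tested.

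Among changed genes 257 differed at least 32-fold, 91 higher and 166 lower, and 58 of them had 0 counts in all libraries of a line. Segments of another genotype carried along with the transgene might give such near-absence. At most 5 of these genes lay in any window of 50 neighbouring tested genes (p = 0.3846 by permutation), which argues against a few long segments as the source of most of them. Segments spread over much of the genome would raise the count per window little. The window test was not tried on simulated data at so low a share of genes (1.2%), so it cannot exclude them. The embryo and oil body median of -0.64 (-0.77 to -0.55 without single libraries) and the aleurone median of -0.21 (-0.23 to -0.18) are far smaller than a shift of 5. Their named members were expressed in both lines, so even a large change in the share of such cells might not reach that shift. These medians therefore cannot decide whether such cells differed. Cells of other parts cannot be told apart from other causes, since the basal transfer layer median was -0.84 but -3.25 without nacRNAi replicate 1, from 3 genes near the floor, and the photosynthesis median of -0.07 lies among members that went both ways. Short or widely spread segments, other cells and an effect of the construct stay open.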
